A study of Macaca fascicularis with 132 samples.

How the data were processed

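RNA was measured in peripheral blood mononuclear cells of cynomolgus macaques (Macaca fascicularis) that were cultured with or without heterodimeric IL-15, the cytokine bound to its receptor alpha chain. Per the labels' protocols, RNA was isolated with a column kit (Qiagen RNeasy Mini) and sequencing libraries of messenger RNA were made with the KAPA mRNA HyperPrep kit. The 132 libraries come from 4 animals, 2 females and 2 males by their labels, in 11 groups. Control cultures were sampled at 0, 2, 6, 12, 24 and 48 h and cultures with IL-15 at 40 ng/ml at 2, 6, 12, 24 and 48 h, with 3 numbered libraries for each animal and group. The series' design text speaks of 6 animals. The 4 given here are analysed, and others are not analysed here.

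The authors deposited 2 tables of whole-number counts per gene for these 132 libraries. One table carries gene IDs of the cynomolgus macaque (38550 rows, 31327 with at least 1 count) and the other gene IDs of the rhesus macaque (35432 rows, 28595 with a count). The counts are not normalized. The aligner, the counting tool, the genome build and the annotation release are not given in the sources used here. The cynomolgus table was used throughout, and the rhesus table served as an alternative. Neither table pairs its gene IDs with symbols, and the reference table used here holds no such IDs, so 0 of the IDs could be matched to a symbol. The 34 lists of genes and the rule for named genes that were fixed before the data were examined need symbols and could not be run. In their place genes were grouped by the times and the direction in which they passed the test. At most 2 IDs that rose and 2 that fell are printed. They were chosen by a rule that was written after the tables were opened and before any test. Among genes with a mean of at least 5 CPM in the higher of both groups, an adjusted p under 0.05 and the same direction in 4 of 4 animals at each of the 5 times, they are the 2 with the highest and the 2 with the lowest log2 fold change averaged over the times. The rule left 68 genes that were higher and 31 that were lower.

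Depth was 16423972 to 87944372 counts per library, with a median of 27185130. Counts of PCR-amplified reads without molecular identifiers are not independent molecules, so the counting error understates the spread. The animal was taken as the unit of replication. Nothing in the labels says whether the 3 numbered libraries of an animal and group are separate cultures or repeated libraries of 1 culture, so their counts were summed, giving 44 sums. No 2 of the 3 libraries agreed within sampling noise. Over the 132 pairs of such libraries, the lowest chi-square per degree of freedom of their counts was 3.57 and the median 14.8, over genes with at least 20 counts in the pair. All tables' columns matched a sample by name.

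The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on the 44 sums, with TMM normalization, filterByExpr on the groups (18197 genes kept), robust estimation, a term for the animal and all 11 groups in 1 fit. Genes with a Benjamini-Hochberg adjusted p under 0.05 were counted. Contrasts were IL-15 against control at each time, control culture against control at 0 h, the difference between the IL-15 effects of 2 times, and a joint test of all 5 times. Females and males were compared with limma 3.58.1 (trend, robust) on each animal's log2 fold change averaged over the 5 times. Log-CPM values used a prior count of 2. Fold changes of single animals, their root mean squares and their correlations were taken over the 10101 genes with a mean of at least 5 CPM.

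The animals pair the samples across groups, as the labels give the same animal in every group. Deviations of the IL-15 and control sums of 1 animal from their group means correlated across genes in 20 of 20 pairs above 0.1 (median r 0.671, lowest 0.52), against a median of -0.226 between animals. Deviations from a group's mean cancel out over its animals. The negative value between animals therefore follows from the value within animals and is not separate support. The library numbers gave little sign of pairing the samples. Libraries with the same number correlated with a median r of 0.0189 (-0.386 to 0.464), and 16 of 60 pairs were above 0.1. Those with other numbers had a median r of -0.0124, and 20 of 120 pairs were above 0.1.

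The column names carry tokens that the labels do not explain (Lib1 or Lib2 with GL66, GL67, GL75, GL76 or merged) and that divide the libraries into 6 sets of 17, 34, 49, 1, 8 and 23. They were treated as possible batches. Each library's root mean square log2 distance to the nearest of its 2 sister libraries had a median of 0.475. Over the limit of 0.769, the median plus 5 scaled median absolute deviations, lay 3 libraries.

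The tests were checked on simulated counts for 4000 genes with the real means and library sizes. All simulated genes had the same dispersion, and the IL-15 effect did not vary between animals, as it may in the data. The shares recovered can therefore be too high for the data, and the shares of false calls too low. For IL-15 against control at 12 h, edgeR recovered 49.3% of genes changed 1.5-fold, 77.6% of those changed 2-fold and 95.5% of those changed 4-fold, with 5.13% false among its calls. DESeq2 recovered 46.3%, 77.6% and 93.9%, with 8.81% false. At an unchanged time edgeR called 0 genes. For females against males, 92.5% of genes whose effect differed 2-fold were recovered. There the animals of a sex shared 1 simulated effect, so this share does not give the power of the test in the data. For the difference between the effects at 12 h and 6 h, limma on the 20 differences of IL-15 and control recovered 87.9% of genes changed 4-fold, 28.4% of those changed 2-fold and 4.48% of those changed 1.5-fold.

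Alternatives fixed before the data were examined were RLE size factors, DESeq2 1.42.0, no filter and a stricter filter on low counts (at least 50 counts in at least 4 sums), no animal term, a block for each animal and time, the 132 libraries entered singly with and without the library number as a block, limma voom with duplicateCorrelation, each comparison fitted alone, each animal left out, each library number alone, the rhesus table and, for the sexes, an edgeR interaction. Chosen after seeing the data were the fit without the 3 libraries that stand apart, the fit with the column-name token as a term, the fits within 1 token and the direction within 1 token of genes called outside it. Figures were drawn with matplotlib 3.10.9.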

Results

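Interleukin-15 (IL-15) is a cytokine that acts on natural killer cells and T cells, and the heterodimer used here joins it to the alpha chain of its receptor. The series asked how the RNA of blood mononuclear cells from cynomolgus macaques changes over time when the cells are exposed to this heterodimer outside the body. Counts per gene were obtained for 12 libraries (4 animals with 3 libraries each) in each of 11 groups. Groups were control cultures at 0, 2, 6, 12, 24 and 48 h and cultures with 40 ng/ml of the heterodimer at 2, 6, 12, 24 and 48 h. Library totals averaged between 23038376 ± 6090403 counts (SD, n = 12 libraries; IL-15, 6 h) and 30728828 ± 8072237 counts (control, 6 h). They ranged from 16423972 to 87944372 counts, and the second deepest library had 47509688 counts. Genes with at least 1 count numbered between 15457 and 21115 per library, and the 20 most abundant genes took 7.99% to 11.5% of the counts. Genes are described in groups, by the time and the direction in which they passed the test, because the tables used here do not pair gene IDs with symbols.

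Time in culture and the animal accounted for most of the differences between the sums of 3 libraries. Over the 40 sums with a matched time, time took 39.6% of the sum of squares of log2 CPM and the animal 29.4%. The heterodimer took 7.85% and its change with time another 6.08%, which left 17.1%. The first principal component of the 44 sums held 29.3% of the variance and the second 11.4%.

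**Figure D1:**
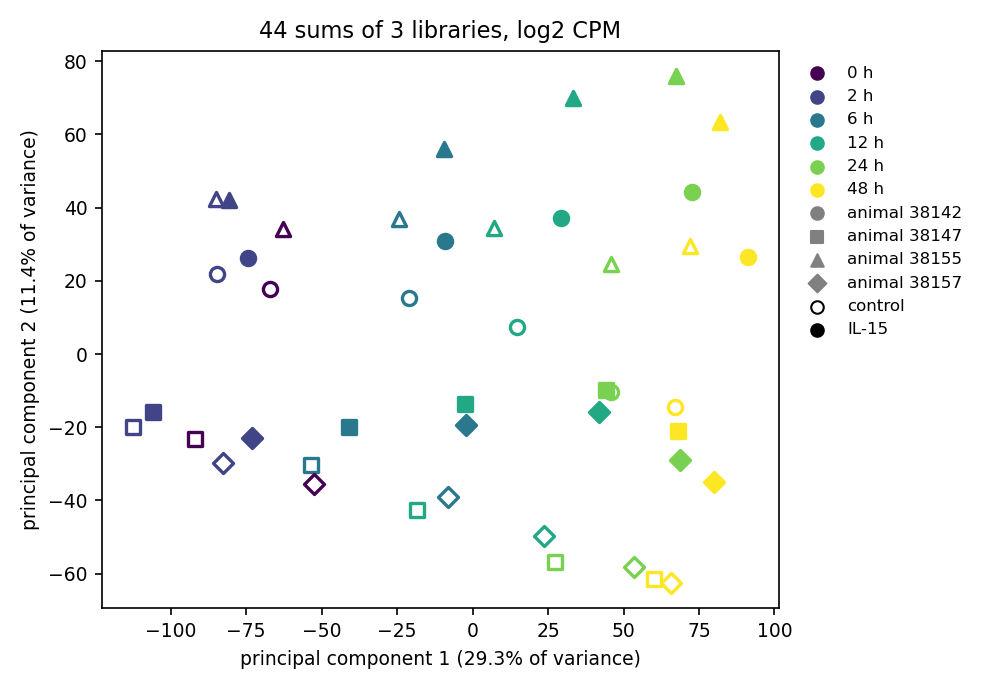
Principal components 1 (x axis) and 2 (y axis) of log2 CPM for the 44 sums of 3 libraries, with 29.3% and 11.4% of the variance, where colour gives the time in hours, the marker shape the animal, open markers control cultures and filled markers cultures with IL-15. From 2 h on, later times of an animal lie farther right, and each filled marker lies above the open marker of the same animal and time, except at 2 h for animal 38155.

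The first comparison asked which genes differed between cultures with and without IL-15 at each time. At 2 h, 303 genes were higher and 90 lower with IL-15, with a median change of 0.47 on the log2 scale (edgeR quasi-likelihood test, adjusted p under 0.05, 18197 genes tested, n = 4 animals). At 6 h, 932 genes were higher and 644 lower. By 12 h the numbers were 3177 higher and 2550 lower, and at 24 h they were 3644 and 3453. At 48 h, 3681 genes were higher and 3635 lower, 40.2% of the genes tested. Changes of at least 1 on the log2 scale were found for 50 genes higher and 5 lower at 2 h, 737 and 580 at 12 h, 871 and 1121 at 24 h, and 1058 and 1206 at 48 h. In the joint test over the 5 times, 9807 genes passed (53.9%).

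Genes that were higher at 2 h had a median of 22 CPM in the control cultures, and those that were lower a median of 34 CPM; at 6 h the medians were 22.2 CPM and 21.5 CPM. Genes that were higher at 12 h had a median of 32 CPM in the control cultures, and those that were lower a median of 13.4 CPM. At 48 h the medians were 23.5 CPM and 9.64 CPM. Most changes were modest. The median fold was 1.4 for genes higher and 1.36 for genes lower at 2 h, and 1.5 and 1.66 at 48 h. Changes of 4-fold or more were seen for 15 genes higher and 1 gene lower at 2 h, and for 425 higher and 257 lower at 48 h. Among the genes higher with IL-15, 2 at 2 h, 8 at 6 h, 17 at 12 h, 13 at 24 h and 14 at 48 h had at most 3 counts over all 4 control sums. Among those lower, 1, 2, 14, 27 and 19 had at most 3 counts over all 4 sums with IL-15.

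**Figure D2:**
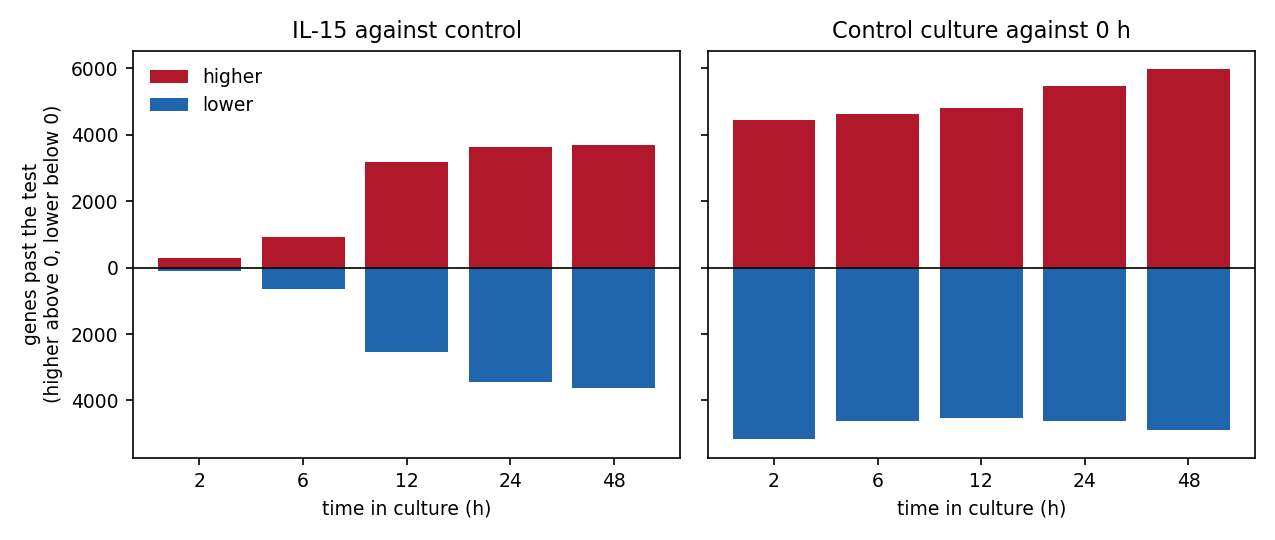
Number of genes (y axis) past the edgeR test at each time in hours (x axis, evenly spaced), higher above 0 and lower below 0, for IL-15 against control (left) and control culture against 0 h (right), with bars as counts of 18197 genes tested in 4 animals. The IL-15 counts go from 303 higher and 90 lower at 2 h to 3681 and 3635 at 48 h, while the culture counts are at 4451 and 5172 already at 2 h.

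These counts moved with the settings of the test. With each comparison fitted alone, 960 genes were higher and 836 lower at 2 h and 1837 and 2274 at 6 h, so that the share higher among the genes called went from 77.1% to 53.5% at 2 h and from 59.1% to 44.7% at 6 h. At 12 h this share was 55.5% as reported, 47.7% with a stricter filter on low counts and 44.7% with libraries entered singly, so neither direction prevailed under all settings. With each animal's pair of sums at 1 time as a block, 475 genes were higher and 212 lower at 2 h, and 1269 were lower at 6 h; with any 1 animal left out, at most 181 were higher and 32 lower at 2 h. For single sets of the column-name tokens, genes were called in the sums of all libraries outside a set, and their direction was taken inside it. The calls and the direction thus share animals. Inside a set the mean of control libraries was set against that of IL-15 libraries without pairing by animal, so differences between animals enter these shares. In Lib2 GL75 at 2 h, for example, IL-15 libraries came from animal 38155 and the control library from animal 38142. In Lib1 GL75 it was the same for 94.5% of these genes at 2 h, 98.8% at 12 h, 98.3% at 24 h and 97.8% at 48 h, against 49% to 77.2% of the genes not called. That set holds 0 libraries with IL-15 at 6 h. In Lib1 GL67 the shares were 94.5%, 99.2%, 89.4%, 96.4% and 95.6% at 2, 6, 12, 24 and 48 h (53.3% to 71.1% of those not called). Lib2 GL75 gave 61.7%, 97.2%, 95.8%, 78.3% and 94.2% (49.2% to 69.1%), and Lib1 GL66 gave 82.5%, 91.6%, 95.9% and 77.7% at 2 to 24 h (52.8% to 69.6%), some of them from 1 library in a group. Lib1 merged, with 1 library per group, gave 87%, 82.7%, 94.2% and 87.7% at 2, 6, 24 and 48 h (54.6% to 68%). Lib1 GL76 holds 1 library and gives no value.

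The 2 IDs with the largest rise averaged over the times were ENSMFAG00000001455 and ENSMFAG00000045925. ENSMFAG00000001455 stood at 24.3 ± 15.1 CPM (SD, n = 4 animals) before culture. With IL-15 it was at 241 ± 20.4 CPM at 2 h against 44.3 ± 13.9 CPM in control cultures, a log2 fold change of 2.44 ± 0.29 (SE; edgeR adjusted p = 2e-06). At 6 h it was at 282 ± 62.5 CPM against 11.8 ± 3.2 CPM, and the difference was widest at 12 h, with a log2 fold change of 4.84 ± 0.33 (adjusted p = 8.1e-13). At 48 h it was still 3.44 ± 0.31 (adjusted p = 8.7e-11). ENSMFAG00000045925 rose from a low level, 1.81 ± 1.45 CPM in control cultures at 2 h against 6.94 ± 5.7 CPM with IL-15. Its log2 fold change went from 1.95 ± 0.34 at 2 h (adjusted p = 0.00084) to 4.42 ± 0.35 at 12 h, where IL-15 cultures held 86.8 ± 61.9 CPM. At 48 h it was 2.78 ± 0.32, against control cultures that had themselves risen to 9.56 ± 7.18 CPM. Both were higher with IL-15 in 4 of 4 animals at every time, which the rule that chose them requires. That rule also requires an adjusted p under 0.05 at each time and takes the largest changes, so these values are not independent support. The call of ENSMFAG00000045925 at 2 h was lost without animal 38142 (log2 fold change 1.96, adjusted p = 0.055).

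The 2 IDs with the largest fall were ENSMFAG00000000349 and ENSMFAG00000035695. ENSMFAG00000000349 rose in control culture, from 3.73 ± 1.21 CPM (SD, n = 4 animals) at 0 h to 52.5 ± 6.58 CPM at 12 h, and with IL-15 it was at 9.22 ± 4.54 CPM at that time. Its log2 fold change with IL-15 was -0.68 ± 0.15 at 2 h (SE; edgeR adjusted p = 0.0094), -2.59 ± 0.16 at 12 h (adjusted p = 1.2e-14) and -1.64 ± 0.15 at 48 h (adjusted p = 8.9e-11). ENSMFAG00000035695 was at 47.7 ± 12.1 CPM before culture and at 55.7 ± 11 CPM in control cultures at 24 h, where IL-15 cultures held 17.5 ± 5.31 CPM. Its log2 fold change was -0.50 ± 0.13 at 2 h (adjusted p = 0.023), -1.68 ± 0.13 at 24 h (adjusted p = 4e-12) and -1.14 ± 0.13 at 48 h (adjusted p = 4.9e-09). Both were lower with IL-15 in 4 of 4 animals at every time, which the same rule requires of them, as it does the adjusted p under 0.05. At 2 h the call of ENSMFAG00000000349 was lost without animal 38147 (log2 fold change -0.61, adjusted p = 0.128), and that of ENSMFAG00000035695 without animal 38147, 38155 or 38157 (log2 fold changes -0.46, -0.53 and -0.47). The latter call was also lost with each animal's pair of sums as a block (log2 fold change -0.5, adjusted p = 0.0572) and did not hold in 9 of 19 alternatives in all (adjusted p up to 0.783).

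**Figure D3:**
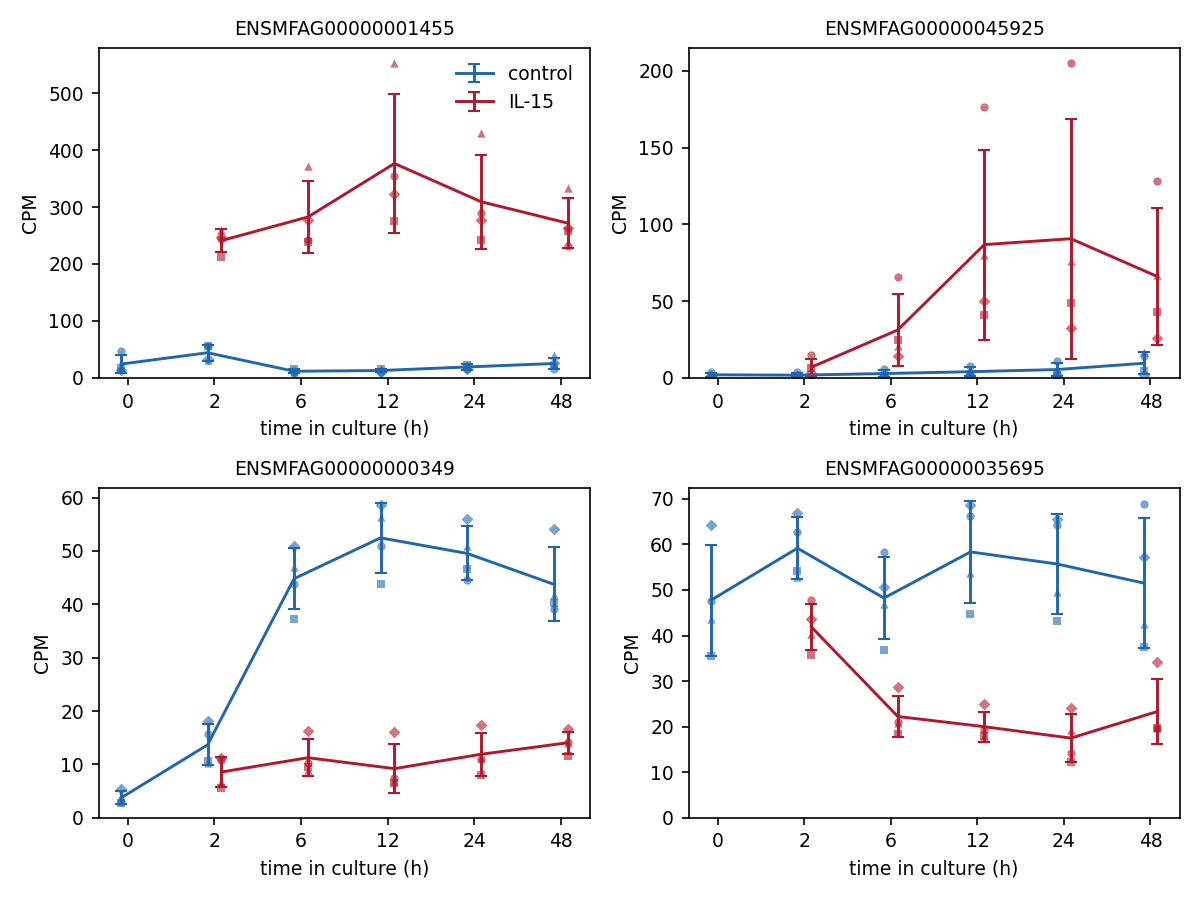
CPM (y axis) of the 2 IDs with the largest rise and the 2 with the largest fall with IL-15 against time in culture in hours (x axis, evenly spaced), where lines are means and bars SD over 4 animals, blue for control and red for IL-15, and points are the sums of 3 libraries of animals 38142 (circles), 38147 (squares), 38155 (triangles) and 38157 (diamonds). ENSMFAG00000001455 reaches 376 CPM at 12 h with IL-15, and ENSMFAG00000000349 reaches 52.5 CPM in control cultures but 9.22 CPM with IL-15.

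The next question was how long these changes lasted. Of the 303 genes higher at 2 h, 42.6% were also higher at 6 h (15.5 genes if the lists were independent), and 246 had the same sign there. Of the 90 genes lower at 2 h, 49 were also lower at 6 h (3.2 if independent). Of the 932 genes higher at 6 h, 826 were higher at 12 h (162.7 if independent), and of the 3177 higher at 12 h, 2631 were higher at 24 h (636.2). Of the 3644 genes higher and 3453 lower at 24 h, 2520 and 2235 were called in the same direction at 48 h (737.1 and 689.8). Across genes of at least 5 CPM, which are not independent replicates, fold changes correlated with r = 0.394 between 2 and 6 h, 0.833 between 6 and 12 h, 0.89 between 12 and 24 h, 0.795 between 24 and 48 h and 0.195 between 2 and 48 h.

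Genes called higher at all 5 times numbered 89, with median log2 fold changes of 0.77, 0.92, 0.95, 0.86 and 0.77 at 2, 6, 12, 24 and 48 h. Genes called lower at all 5 times numbered 37, with medians from -0.49 at 2 h to -0.73 at 12 h. With any 1 animal left out these sets held 36 to 59 and 13 to 17 genes. At 12 h, 2312 genes were first called higher and 1986 first called lower. Their median log2 fold changes were 0.18 and -0.21 at 6 h and 0.48 and -0.58 at 12 h, and the time of a first call is where a gene crossed the threshold, not where its effect was shown to change. Of these, 1265 and 1042 were called in the same direction at 48 h. The 959 genes first called higher at 48 h had a median log2 fold change of 0.15 at 24 h and 0.56 at 48 h. Calls in both directions at different times were made for 200 genes. Among them, 17 genes were higher at 2 h and lower at 48 h, and 8 lower at 2 h and higher at 48 h. In each of these 25 the difference between the effects at both times passed the test, which their choice by opposite effects that each passed makes nearly certain.

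**Figure D4:**
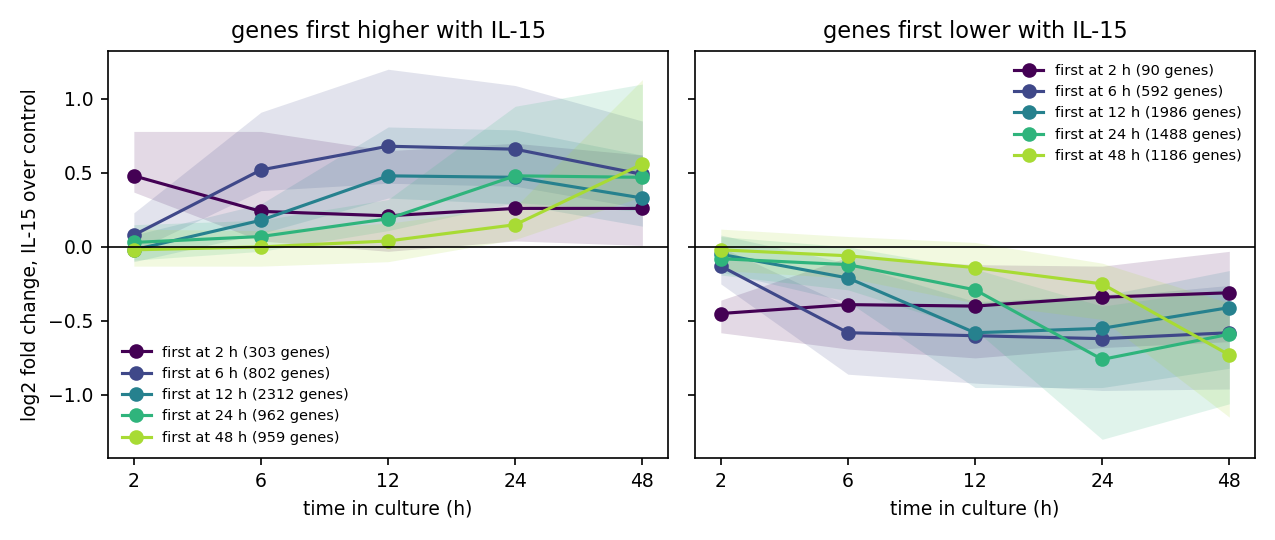
Median log2 fold change of IL-15 over control (y axis) at each time in hours (x axis, evenly spaced) for genes grouped by the time at which they were first called higher (left) or lower (right), where shading spans the 25th to 75th percentile of the genes, and the value at a group's own first time is raised by the choice of its genes. The 303 genes first higher at 2 h go from a median of 0.48 at 2 h to 0.24 at 6 h, and the 802 first higher at 6 h have medians of 0.52 at 6 h and 0.68 at 12 h.

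Effects at different times were compared directly. Between 2 and 6 h the effect of IL-15 differed for 295 genes, moving up for 164 of them (edgeR quasi-likelihood test of the difference, adjusted p under 0.05). Between 6 and 12 h it differed for 18 genes, and between 12 and 24 h it moved up for 96 and down for 6. Between 24 and 48 h it differed for 551 genes, up for 420 of them. Between 2 and 48 h it differed for 3978 genes, up for 2190 and down for 1788. Among the genes behind these numbers were 148 that were higher at 6 h with a greater effect than at 2 h, and 33 that were higher at 2 h with a smaller effect at 6 h. At 48 h, 378 genes were higher with a greater effect than at 24 h and 66 were lower with a greater fall than at 24 h. For ENSMFAG00000001455 the effect was 2.13 ± 0.40 (SE, log2) greater at 6 h than at 2 h (adjusted p = 0.0026). For ENSMFAG00000000349 the difference between 6 h and 2 h was -1.35 ± 0.22 (adjusted p = 0.00025). With each animal's pair of sums at 1 time as a block the counts were 666, 197, 186 and 1161 for the 4 successive steps. On the 8 differences of both times alone, paired by animal, limma called 0 genes for each of these 4 steps, with 3594, 3553, 1622 and 3194 at an unadjusted p under 0.05, and 1879 between 2 and 48 h. Without animal 38142, edgeR called 0 for the steps from 6 to 12 h and from 12 to 24 h, with 1093 and 772 genes at an unadjusted p under 0.05. It called 70 between 2 and 6 h, 236 between 24 and 48 h and 1863 between 2 and 48 h without that animal. Without 38147 it called 0.604% of genes between 2 and 6 h, 7 genes between 6 and 12 h, 30 between 12 and 24 h and 312 between 24 and 48 h. Without 38155 the counts were 95 between 2 and 6 h, 43 between 12 and 24 h and 332 between 24 and 48 h. Without 38157 they were 93 between 2 and 6 h and 6 between 6 and 12 h. Counts that moved less are not listed. The highest with 1 animal left out was 23 between 6 and 12 h, against 18 with all animals. Between 12 and 24 h it was 0.565% of genes against 0.561%, and between 24 and 48 h 532 genes against 551.

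Over all genes tested, 29.5% at 2 h, 41.2% at 6 h, 50% at 12 h, 48.9% at 24 h and 53% at 48 h had the same sign of the IL-15 effect in 4 of 4 animals, against 12.5% by chance. Among the genes called, which the test picks in part for a consistent sign, the shares were 99%, 98.9%, 95.5%, 90.9% and 92.2%. Across genes of at least 5 CPM the fold changes of 2 animals correlated with a median r of 0.57 at 2 h (0.32 to 0.69 over the 6 pairs of animals), 0.78 at 6 h, 0.85 at 12 h, 0.76 at 24 h and 0.8 at 48 h. The root mean square log2 fold change per animal was 0.241 ± 0.021 at 2 h (SD, n = 4 animals), 0.378 ± 0.074 at 6 h, 0.605 ± 0.104 at 12 h, 0.683 ± 0.099 at 24 h and 0.712 ± 0.09 at 48 h. It was greatest in animal 38155 at 6 h (0.488), 12 h (0.752) and 24 h (0.79), and in animal 38142 at 48 h (0.825).

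Culture without IL-15 is the background of each of these comparisons, and it changed more genes than IL-15 did at each time. Against 0 h, 4451 genes rose and 5172 fell by 2 h, 4638 rose and 4632 fell by 6 h, 4797 and 4526 by 12 h, 5473 and 4616 by 24 h, and 5976 and 4899 by 48 h (edgeR quasi-likelihood test, adjusted p under 0.05). At 2 h the median of all genes lay at -0.131 on the log2 scale with TMM and at -0.094 with RLE, and the excess of genes that fell over genes that rose there is relative to that scaling. The root mean square log2 change per animal was 0.825 ± 0.023 at 2 h (SD, n = 4 animals), 0.761 ± 0.024 at 6 h, 0.838 ± 0.042 at 12 h, 0.966 ± 0.042 at 24 h and 1.127 ± 0.098 at 48 h. Fold changes of 2 animals correlated with a median r of 0.85 to 0.91. All 5 comparisons share the same 0 h sums, whose chance values enter each of them.

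The response of females was set against that of males, with 2 animals of each sex. The effect averaged over the 5 times was lower in females for 3 genes and higher for 0 (limma, adjusted p under 0.05). At an unadjusted p under 0.05, 1472 genes passed, and the edgeR interaction of sex and treatment called 0, with 1401 at an unadjusted p under 0.05. The IDs of these 3 genes are not given. Their mean log2 fold changes were -1.59, -2.26 and -1.29 in females and -0.14, -0.42 and 0.25 in males, at means of 500, 10.8 and 45.7 CPM, with adjusted p of 0.037, 0.022 and 0.012. A permutation of 2 animals against 2 cannot give a p under 0.333, and sex cannot be parted from other differences between these animals.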

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

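The tests of the spread between animals and of the tokens within 1 token were chosen only after the result was seen, and the test of splits for differences between times was changed after a first form had been run.

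The effect of IL-15 differed between times for many genes. Between 2 and 48 h it differed for 21.9% of the genes tested (edgeR, adjusted p under 0.05; 3978 genes), between 2 and 6 h for 1.62% (295), between 6 and 12 h for 0.0989% (18), between 12 and 24 h for 0.561% (96 up, 6 down) and between 24 and 48 h for 3.03% (551). Among the 4 printed IDs, the effect on ENSMFAG00000001455 was greater by 2.13 on the log2 scale at 6 h than at 2 h. For ENSMFAG00000000349 the effect at 6 h minus that at 2 h was -1.35, and the effect at 48 h minus that at 2 h was -0.96. For ENSMFAG00000035695 the effect at 48 h minus that at 2 h was -0.65. Females and males differed in the averaged effect for 3 genes, 0.0165% of those tested.

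Among 85 groups of 4 animals, 6 held an animal far from the other 3 for a printed ID, where chance gives about 1 in 20, or 4.2. Animal 38142 stood at 46.9 CPM of ENSMFAG00000001455 before culture and at 3.97 CPM of ENSMFAG00000045925 in control culture at 2 h. Animal 38147 had a log2 fold change of 3.39 for ENSMFAG00000001455 at 24 h. Animal 38157 was at 16.4 CPM (6 h) and 16 CPM (12 h) of ENSMFAG00000000349 and at 34.2 CPM (48 h) of ENSMFAG00000035695 with IL-15.

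The number of genes that differed with IL-15 rose from 2 h to 24 h, 18.1-fold as reported and 3.07-fold with each comparison fitted alone (1796 and 5519 genes), the lowest of all fits run; the highest ratio was 72.4, with library number 1 alone. A smaller spread between the animals at 24 h is argued against, since the SD of the 4 animals' log2 fold changes (median over genes of at least 5 CPM) was 1.756 times that at 2 h. The fit as reported estimates the spread of a gene over all groups together. With a smaller spread at 2 h, this can lower the count there (393 genes as reported, 1796 alone) and raise it at 24 h (7097 and 5519). Part of the 18.1-fold rise can therefore come from the shared fit. For an unequal mix of the column-name tokens, the ratio with the token as a term on single libraries was 5.58. That lies between both bounds set beforehand (5 and 10), so that test leaves it open. Single libraries without the token gave 6.13. Within single tokens the ratio was 6.35 (Lib1 GL75) and 19.7 (Lib1 GL67). At 24 h, however, only animal 38155 had libraries with and without IL-15 in either token. With the animal as a term, the 24 h counts there rest on that animal's sister libraries, so these ratios leave the mix open too. A longer exposure to the cytokine, which the design names, stays open and was not tested, since exposure and time in culture run together.

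Chance division of the samples was tested by limma with the animal as a block, over 32 splits of the 8 sums of both groups that allowed a fit. The animals pair the sums, and only 8 of these splits part the pair of every animal, too few for a share under 0.05; the others keep the pairs of 2 animals together, so that these 2 add nothing to the estimated difference. For IL-15 against control at 2, 6, 12, 24 and 48 h, 1 split, the real one, gave as many genes. The real splits gave 1114, 3912, 6023, 5586 and 6597 genes, and the highest other gave 0, or 1 at 24 h. For control culture against 0 h the real splits gave 9408, 9367, 8270, 8548 and 8474 genes and the highest other 0. Among the 8 splits the highest other gave 0 in each of the 10 comparisons.

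For differences between times, the 20 differences of IL-15 and control were fitted together and the 8 of both times were split in 32 ways. Here too only 8 of them part the pair of every animal, too few for a share under 0.05. Each time 1 split, the real one, gave as many genes. The real splits gave 754 (6 against 2 h), 222 (12 against 6 h), 192 (24 against 12 h), 1194 (48 against 24 h) and 5749 genes (48 against 2 h), and the highest others 1, 2, 1, 388 and 1 (at most 1 among the 8). A first form of the test, on the 8 differences alone, had called 0 genes in 4 of these 5 comparisons and 1879 for 48 against 2 h, which led to the form with all 20. For the joint test, control and IL-15 were relabelled within animal and time, and 1 of 100 relabellings, the real one, gave as many genes (10036). Each time of an animal was relabelled on its own, though the animal is the unit of replication. The test therefore speaks only to labels that vary freely between the times of an animal. It does not exclude chance with the animal as the unit. The highest other gave 8507, in a relabelling where 3 times kept the 4 animals alike; where 0 times did so, the highest of 40 gave 1.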

How the results depend on the processing

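The fits without 3 libraries, with the token as a term, within 1 token and outside 1 token were chosen only after the result was seen. With RLE size factors, no filter, the stricter filter or the rhesus table, each of 27 counts stayed within 1.5 times, and genes called with IL-15 or in culture had the same sign in at least 99.4% of cases under every alternative on the cynomolgus table but the values within 1 token, which gave down to 61.7% for genes called outside it. The value of 61.7% sets IL-15 libraries of animal 38155 against a control library of animal 38142, so differences between animals enter it. All but the values for genes called outside a token use the counts that made the calls, or a part of them, so this agreement in sign is not independent support. Calls were kept less often than signs. Of the genes called at 2 h, 15.5% were also called without the animal term, 16% with library number 1 alone and 29% without animal 38142, and at 6 h 24.7% without the animal term. The gene list alternatives (an estimated correlation, fry) and the rule for named genes by symbol were not run, since no symbols were matched. The share of genes higher among those called at 2 h went from 77.1% to between 53.5% (comparisons fitted alone) and 91.8% (no animal term), and at 6 h from 59.1% to between 44.7% and 76.4% under the same 2 settings. At 12 h it went from 55.5% to between 44.7% (libraries entered singly) and 70.3% (no animal term), over 50% in 14 of 21 settings. At 24 h it was 51.3% with TMM, 46.7% with RLE, 46.1% with DESeq2 and 47.9% in the rhesus table, and at 48 h 50.3%, 49.6%, 49% and 45.7%. Depth limits genes near the floor. Results whose number of genes moved by over 1.5 times follow, as percent of the genes each setting tested (higher, then lower). Other percents can also have moved by over 1.5 times, as the settings tested different numbers of genes. Where fewer samples do not give the cause, it was not tested.

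As reported, IL-15 against control gave 1.67%, 5.12%, 17.5%, 20% and 20.2% higher and 0.495%, 3.54%, 14%, 19% and 20% lower at 2, 6, 12, 24 and 48 h, the differences between times (6 against 2 h, 12 against 6 h, 24 against 12 h, 48 against 24 h, 48 against 2 h) 1.62%, 0.0989%, 0.561%, 3.03% and 21.9%, the joint test 53.9% and the sexes 0.0165%. Without an animal term (no block) these were 0.308%, 1.64%, 9.35%, 11.9% and 11.9% higher, 0.0275%, 0.506%, 3.96%, 6.59% and 7.53% lower, 0.0989%, 0%, 0.121%, 0.896% and 6.87% and 27.7%, with 15.2% and 15.6% lower in culture at 6 and 12 h. With a block for each animal and time, 2.63% were higher and 1.17% lower at 2 h, 7.02% lower at 6 h, and the first 4 differences gave 3.68%, 1.09%, 1.03% and 6.42%, while the set lower at all 5 times went from 37 to 81 genes; this block was not run for the culture counts. Libraries entered singly gave 5.66% and 3.73% at 2 h, 12% and 11.7% at 6 h, 28.3% lower at 12 h and 10.8%, 11%, 4.46%, 17.7% and 42% for the differences. The library number, which gave little sign of pairing the samples, was also added as a block. Libraries entered singly then gave 5.76% and 3.74% at 2 h, 12.1% and 11.7% at 6 h, 28.4% lower at 12 h and 10.9%, 11.1%, 4.47%, 17.7% and 42.1%. With the token as a term they gave 6.41% and 3.96% at 2 h, 10.7% and 11.3% at 6 h, 28.8% lower at 12 h and 10.2%, 10.8%, 4.71%, 16.8% and 41.6%. DESeq2 gave 0.896% lower at 2 h and 2.52%, 0.857%, 0.94% and 4.73% for the first 4 differences. Limma voom with duplicateCorrelation (consensus correlation 0.297) gave 1.38% lower at 2 h, 6.23% lower at 6 h and 4.68%, 4.05%, 2.07% and 9.59%. Comparisons fitted alone gave 6.18% and 5.38% at 2 h, 11.6% and 14.3% at 6 h and 5.73% and 1.73% for the first 2 differences.

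Library number 1 alone gave 0.346% and 0.0503% at 2 h, 2.41% and 1.31% at 6 h, 11.5% and 7.7% at 12 h, 13.2% lower at 24 h, 14.6% and 13.4% at 48 h, 19% lower in culture at 12 h, differences of 0.308%, 0.0314%, 0.245%, 1.54% and 10.7%, 38.1% in the joint test and 0.0943% between the sexes. Number 2 alone gave 0.564% and 0.0868% at 2 h, 2.54% and 1.77% at 6 h, 11.4% and 9.79% at 12 h, 0.595%, 0.031% and 0.174% for the first 3 differences, 14.7% for 48 against 2 h and 0.0372% between the sexes. Number 3 alone gave 14.2% and 13.5% at 24 h, 15.3% higher at 48 h, 0.219%, 1.76% and 14.3% for the last 3 differences and 0.0313% between the sexes. Without the 3 libraries that stand apart, 0.17% differed between 6 and 12 h and 0.044% between the sexes. The edgeR interaction of sex and treatment called 0, with 1401 genes at an unadjusted p under 0.05.

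With 1 animal left out, 0.558 to 1% were higher and 0.0985 to 0.177% lower at 2 h, 2.47 to 3.64% and 1.62 to 2.85% at 6 h, 11 to 15.2% and 8.17 to 14.1% at 12 h, 13.6 to 17.2% and 13.7 to 18.4% at 24 h, 13.9 to 18.5% and 13.5 to 17.8% at 48 h. The differences gave 0.383 to 0.604%, 0 to 0.127%, 0 to 0.565%, 1.29 to 2.92%, 10.2 to 18.7%, the joint test 39.1 to 49.1% and the sexes 0 to 0.0384%. Both zeros between times came without animal 38142 (1093 and 772 genes at an unadjusted p under 0.05; 706 behind the 0 without an animal term), and limma on the sexes gave 0 without 38142 (1535) or 38155 (821) and 0.0384% without 38157; each of these sets 1 animal of a sex against 2 of the other, and the lone animal is assumed to vary like the other sex. The sets of genes higher and lower at all 5 times (89 and 37) held 19 and 2 genes without the animal term and 252 and 192 with the token as a term, the lowest and highest but for 258 higher with the library number as a block.

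No printed ID changed sign under the 19 alternatives. ENSMFAG00000001455 passed at each time in all 19. At 2 h ENSMFAG00000045925 did not pass in 2 (adjusted p up to 0.615), ENSMFAG00000000349 in 4 (up to 0.614) and ENSMFAG00000035695 in 9 (up to 0.783), the highest each time without the animal term. At 6 to 48 h these 3 passed in all 19.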

Other observations

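The tests of culture and IL-15 change at 2 h and 48 h alone, and of a wrong label and of depth for the library that stands apart, were chosen only after the result was seen.

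At 48 h, genes that changed in control culture and with IL-15 fell unevenly into 4 groups. Genes that rose in culture and were lower with IL-15 numbered 1683 (1193.8 if the lists were independent), and those that fell in culture and were higher with IL-15 numbered 1116 (991). Those that rose in culture and were higher with IL-15 numbered 1195 (1208.9), and those that fell and were lower 739 (978.6). ENSMFAG00000000349, which rose in culture and less so with IL-15, is of the first group. At 12 h the same 4 groups held 995 (672.2), 994 (790.2), 801 (837.5) and 515 (634.2) genes.

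Both changes are taken against the same control cultures, which may produce such a pattern. Simulated groups with no effect gave a correlation across genes of -0.523 at 2 h and -0.5 at 48 h, against -0.197 and -0.176 observed. A value near -0.5 follows from the shared control alone when there is no effect, so it does not measure how much of the observed pattern the controls make. The covariance was -0.0372 at 2 h and -0.182 at 48 h, against -0.111 and -0.106 simulated, a difference of 0.0743 and -0.0763. The simulated covariance at 2 h exceeds the observed one in size, so the simulated noise does not match the data and these differences decide nothing. With the culture change from 2 animals and the IL-15 change from the other 2, no control is shared. At 2 h the 6 correlations had a median of 0 (-0.014 to 0.015; -0.055 to 0.034 among genes of at least 5 CPM), which the same control cultures would give. At 48 h the median was -0.137 (-0.199 to -0.065; -0.155 to -0.012 among those genes) and the median covariance -0.142. All are negative, though the 6 reuse the same animals, which argues against the same control cultures as the whole cause at 48 h. By the bound of -0.05 both times stay undecided, as do all 5 times together, since 1 time had all 6 correlations below -0.05. Noise of genes with few counts stays open as well, since among genes of at least 5 CPM the median correlation lay below -0.05 at 3 of the 5 times. Taken over all genes, IL-15 cultures did not stay closer to the uncultured state. Their distance from 0 h at 48 h was 1.006 or more times that of control cultures in 4 of 4 animals. The mean ratios were 1.018, 1.072, 1.178, 1.183 and 1.1 at 2, 6, 12, 24 and 48 h. Any change made by IL-15 adds to this distance, so it cannot tell whether IL-15 held back part of the culture changes, and that stays open.

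Library 1 of the control 48 h cultures of animal 38142 lay 1.125 on the log2 scale (root mean square) from its nearest sister library, against a median of 0.475. It lay 1.16 from the mean of libraries 2 and 3 of its own culture. The nearest other culture of the series, the same animal's control at 24 h, was farther than its own by 0.044, at 1.203. Both distances are large and close to each other, so they do not decide on a wrong label. The library's total over the rhesus IDs was 1.004 times that over the cynomolgus IDs, against 1.018 and 1.015 in libraries 2 and 3. Depth is argued against, since 18 libraries with fewer counts had a median distance 0.464 times its own. A mixture with another culture of the series is argued against, since the best of 43 removed 6.91% of its squared deviation. The design gives no biological explanation for 1 library, and none was tested. Library 2 of the control 0 h cultures of the same animal (0.933) and library 3 of the control 2 h cultures of animal 38157 (0.839) also lay over the limit; without all 3, 251 genes were higher and 67 lower at 2 h.

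Hypotheses on the animals were tested too. If the labelled sexes hold, some genes should have counts in both males alone, and 6 genes had counts in all male libraries and at most 3 in any female library, against at most 2 genes for any other pair of animals. If the animals differ in their response beyond the spread of their 3 libraries, single libraries should show it. At 48 h, 12% of genes (1688) passed edgeR's test of animal and treatment over the 24 single libraries, and at 2, 6, 12 and 24 h 5, 727, 3125 and 3438 genes did. As nothing says that the 3 libraries are separate cultures, this spread can be technical.

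The total over the rhesus IDs exceeded that over the cynomolgus IDs in each library, with ratios from 1.004 to 1.026.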
